A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

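Small subunit (SSU) processomes, the nucleolar particles in which the 18S rRNA precursor is folded and cut, had been purified from Saccharomyces cerevisiae through a TAP tag on Utp10, a subunit of the particle. The cells carried either wild-type (WT) Has1, a DEAD-box RNA helicase of ribosome assembly, or Has1 with the H375A substitution. Per the labels' protocols, cells were grown in rich medium to mid-log phase and treated with 1% dimethyl sulfate (DMS) at 30 °C for 5 min, and RNA was recovered with phenol and chloroform for DMS-MaPseq. In this assay DMS methylates the pairing face of accessible A and C bases, and reverse transcription through a methylated base leaves a mutation in the cDNA. Each DMS library had an untreated control of the same genotype and replicate number. The series had 16 libraries, 4 per combination of genotype and treatment, described by the submitters as biological replicates.

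The deposited profiles gave counts for every nucleotide, namely mutated reads, reads covering it, and reads of sufficient quality covering it (effective depth). The authors also gave a mutation rate as a fraction, which per the file headers and the values was the mutated reads divided by the effective depth, without subtraction of the untreated rate. Per the file headers, reads were placed on a pre-rRNA sequence that ran for 6647 nt from the 5' end of the transcript to the 3' end of 25S. The aligner, the mutation caller, their versions and the read filters were not given in the sources used here. Read filters and the caller's handling of deletions and of neighbouring mutations act on all rates, and PCR duplicates were not identified as molecules, so counting intervals cover counting error only. The many genomic copies of the rDNA were read as 1 sequence. Positions are numbered from 1 at the 5' end of the profile, and 18S, found by its terminal sequences, took positions 701 to 2500. Lengths of 18S, 5.8S and 25S in the profile, 1800, 158 and 3396 nt, matched those of the rRNA genes in the RefSeq annotation of assembly R64, which was used for names and lengths alone; no genome coordinates are given because no build was named. The 3' external transcribed spacer lay outside the profile and was not analysed here.

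Sites from the 5' end to the A2 cleavage site (position 2712) were taken as the SSU part of the pre-rRNA. Of its 1236 A and C sites, those with an effective depth of at least 100 in each of the 16 libraries were used. A depth minimum of 1000 had been fixed before the data were examined, together with the tests, regions, the rule for named sites and most alternatives; it left 0 sites, since the deepest site had 975 reads in its shallowest library, so the lower minimum of 100, which had been listed beside it, was used throughout. Sites were kept where the mean DMS rate was at least 0.2 percentage points above the mean untreated rate and the untreated rate was under 5%, which left 725 of the 1154 sites with the depth. Positions of the A0 and A2 cleavage sites and of the modified bases of 25S were entered from general knowledge after the depths had been seen, and the segments paired with the U3 snoRNA after the called sites had been seen.

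Mutated reads were compared between genotypes with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the log of the effective depth and of a scaling factor per library as offset, on the 8 DMS libraries. The scaling factor was the median ratio of a library's rate to the geometric mean over libraries, over the 594 sites with mutated reads in all 8, so changes are relative to the median site. An exploratory fit with a robust dispersion and another scaling had been run before the planned one. P-values were adjusted by the Benjamini-Hochberg method, and sites with an adjusted p under 0.05 were called. Named sites were those called, at least 1.5 times higher or lower, and without overlap between the 4 libraries of either genotype, up to 12 in each direction by the change in background-subtracted rate; 14 sites met the rule. Standard errors (SE) of log2 changes were taken from the test statistic. The same test was run on the 295 sites of 25S that passed the filters, with their own scaling, and, over all 4 bases and without scaling, on the untreated libraries at 554 sites with at least 10 mutated reads on average. Regional values were log2 mean scaled rates over the 725 sites by domain and by 100-nt window, tested with limma 3.58.1. Mean rates by base, depth of each region over that of 18S, and untreated rates at modified bases were compared with exact two-sided permutation tests, for which 4 libraries against 4 give no p below 0.0286. Of the snoRNA pairing lists, only the U14 site in 18S was used, because no snoRNA sequences were in the reference used here; as a lone list it was tested by exact permutation in place of limma. Tests were checked on simulated counts. These were drawn with edgeR's fitted dispersions for sites and with a fixed dispersion for domains, without further differences among replicates. Recovery and false calls in the real libraries can therefore differ from those given here. With 725 sites and 200 changed ones, 30% of 1.5-fold and 65% of 2-fold changes were recovered, with 5 false calls among 100. With 295 sites of 25S, 0% and 3.33% were recovered, and with 554 untreated sites 2% and 12%, with 2 false calls among 9. A domain shift of 0.5 on the log2 scale was recovered in 20 of 20 simulations, with 5 false calls in 100 tests of unshifted domains; smaller shifts, such as those observed, were not simulated.

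Alternatives covered the scaling, the filters on signal and depth, DESeq2 1.42.0, a quasi-binomial model per site, a genotype by treatment interaction over 16 libraries, limma on background-subtracted rates, the replicate number as a block, and leaving out each replicate. Libraries of a group were compared for duplication; none were identical, and chi-square per degree of freedom between replicates ran from 1.14 to 2.08.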

Results

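DMS-MaPseq profiles of the pre-rRNA were obtained from SSU processomes purified through Utp10 from cells with WT Has1 or Has1-H375A, to compare the folding of the rRNA in the particles that each genotype accumulates. There were 4 DMS-treated and 4 untreated libraries per genotype. Total mutated reads ran from 5955 to 166512 per library. Median effective depth over 18S was 359 to 1568 reads in the WT DMS libraries and 333 to 989 in H375A replicates 1, 2 and 4, against 4654.5 in H375A replicate 3. At a depth of 333 reads a rate of 1% has a 95% Wilson interval of 0.307% to 2.61%, and at 4654.5 reads of 0.760% to 1.34%; these intervals cover counting error only. The 5' external transcribed spacer (5' ETS), which is cut away during 18S maturation, had 1.68 to 2.98 times the median depth of 18S in the DMS libraries. Replicate 1 of both genotypes stood apart from the other replicates, with scaling factors of 0.847 in WT and 0.864 in H375A against 1.03 to 1.13 in the rest.

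DMS raised mutation rates mainly at A and C, the bases whose pairing face it methylates. At A sites of the SSU part, the mean rate was 1.23% ± 0.16 (SD, n = 4) in WT DMS libraries and 0.426% ± 0.029 in untreated ones, a 2.89-fold difference. In H375A it was 1.19% ± 0.16 and 0.420% ± 0.015, 2.83-fold. At C sites the rates were 0.806% ± 0.049 and 0.376% ± 0.012 in WT, and 0.807% ± 0.028 and 0.384% ± 0.026 in H375A. G rose by 1.14-fold in WT and by 1.12-fold in H375A, and U by 1.09-fold in WT. Each of these 7 differences separated all DMS from all untreated libraries (exact permutation p = 0.0286, adjusted over 12 tests 0.049), while U in H375A, 0.443% against 0.416%, did not pass (exact permutation p = 0.114). Taken as pairs of the same genotype and replicate, the DMS library was the higher in 4 of 4 pairs for each base and genotype, U in H375A included, although an exact test of 4 pairs gives no p below 0.125. With the median rate in place of the mean the adjusted values rose to between 0.069 and 0.086 and no longer passed. Between genotypes the DMS rate did not differ detectably at A (exact permutation p = 0.486), C (0.914), G (0.286) or U (0.057).

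Relative to the median site, DMS reactivity differed between genotypes at 26 of 725 A and C sites of the SSU part by edgeR's quasi-likelihood test, 8 of them higher and 18 lower in H375A. In 18S, 2 sites rose and 7 fell. Among the called sites, the largest log2 change fitted by edgeR, and the largest change in percentage points, was at A1839, nucleotide 1139 of 18S, at the 3' end of the central domain. Its scaled rate fell from 8.32% ± 2.67 in WT to 3.01% ± 0.85 in H375A (SD, n = 4; log2 change -1.57, SE 0.19, edgeR adjusted p = 1.22e-08), with untreated rates of 0.572% and 0.493% and depths of 188 to 3983 reads. In the 3' major domain, which folds into the head of the subunit, 4 of 141 sites changed, all between positions 1901 and 2000, where the share of called sites did not pass (4 of 25, Fisher's exact test, adjusted p = 0.0887). C1946 (18S 1246) fell from 4.38% ± 0.74 to 1.91% ± 0.84 (log2 change -1.45, SE 0.26, edgeR adjusted p = 0.00016), while A1944 (18S 1244) rose from 1.67% ± 0.45 to 3.59% ± 0.95 (log2 change 0.94, SE 0.28, edgeR adjusted p = 0.038). Untreated rates at A1944 were high, 1.15% in WT and 1.26% in H375A, which left 0.519 percentage points above background in WT. The adjacent A1926 and A1927 (18S 1226 and 1227) fell from 2.01% ± 0.41 to 0.466% ± 0.367 and from 1.94% ± 0.45 to 0.867% ± 0.230. By the ratio of mean rates A1926 fell further than A1839, 4.30-fold against 2.76-fold, with a fitted log2 change of -1.49 and 0 mutated reads among 200 in H375A replicate 1. In the 5' domain, which forms much of the body of the subunit, 4 of 219 sites changed. C717, at nucleotide 17 of 18S, rose from 0.991% ± 0.243 to 2.50% ± 0.58, C839 (18S 139) fell from 3.49% ± 0.47 to 1.55% ± 0.43, and A1215 (18S 515) fell from 4.12% ± 0.67 to 2.60% ± 0.39. Among these sites, leaving out a library ended some calls (edgeR adjusted p in brackets): without WT replicate 2 those of A1215, A1926, A1927 and A1944 (0.0983 to 0.263), without WT replicate 3 those of A1215, A1927 and A1944 (0.0677 to 0.0969), without WT replicate 4 that of A1944 (0.101), without H375A replicate 2 those of A1927 and A1944 (0.0951 and 0.297), and without H375A replicate 3 those of A1215, A1926 and A1927 (0.0649 to 0.487). None of the 48 tested sites of the 3' minor domain or the 26 of ITS1 up to A2 was called.

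The 5' ETS held 17 of the 26 called sites, 6 of which rose and 11 fell, among 161 tested. This was a larger share than elsewhere (odds ratio 7.25, Fisher's exact test, two-sided, adjusted p = 1.07e-05), but the stretch was deeper. With the 5' ETS thinned in each library by the ratio of its median depth to that of 18S, the share was smaller and no longer passed, with a median of 5.5 of its 161 sites called over 20 draws and a median odds ratio against 18S of 1.99, from 6.91 before (Fisher's exact test, median p = 0.256). The genotypes overlapped at 11 of the 17 called sites of the 5' ETS, against 1 of the 9 in 18S, and neighbouring sites are not independent. Calls were concentrated at positions 201 to 300, with 6 of 22 sites, and 301 to 400, with 7 of 35 (Fisher's exact test, adjusted p = 0.0015 for both). These tests were against all other sites at full depth, and were not repeated with thinned reads. Of the called sites in these windows, only C300, A302, C311 and C326 had no overlap between genotypes. Rises and falls alternated there over short distances. C300 fell from 2.28% ± 0.45 to 1.09% ± 0.24 and A302 from 1.79% ± 0.27 to 0.873% ± 0.539, while C311 rose from 1.25% ± 0.50 to 2.79% ± 0.67 and C326 from 0.568% ± 0.349 to 1.44% ± 0.36. Outside this stretch C87 fell from 1.10% ± 0.11 to 0.564% ± 0.019 and A473 from 1.22% ± 0.08 to 0.581% ± 0.268. In H375A the untreated rates of C87 and A473 were 0.399% and 0.367%, so their DMS rates there lay near background. Leaving out a library ended the call of C87 without WT replicate 2 (edgeR adjusted p = 0.149), WT replicate 4 (0.0594) or H375A replicate 2 (0.0806), those of C87, A302 and A473 without WT replicate 3 (0.0783 to 0.0871), and those of C87, C300, A302, C326 and A473 without H375A replicate 3 (0.0649 to 0.193). A473 lies in the segment that pairs with the 5' hinge of the U3 snoRNA, a base-pairing partner that holds the pre-rRNA open in the processome.

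**Figure D1:**
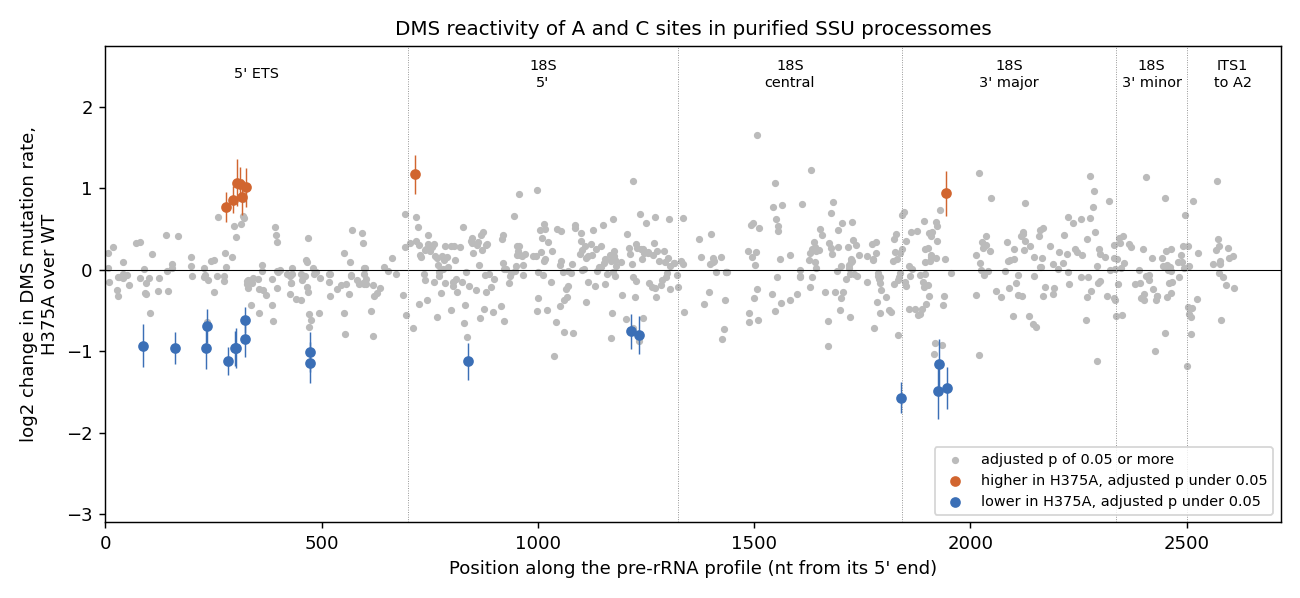
Log2 change in DMS mutation rate, H375A over WT, at the 725 tested A and C sites against position along the pre-rRNA in nt; coloured points are the 8 sites that rose and the 18 that fell, with bars for the SE. Of the 26 called sites, 17 lie in the 5' ETS, which was read more deeply than 18S.

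**Figure D2:**
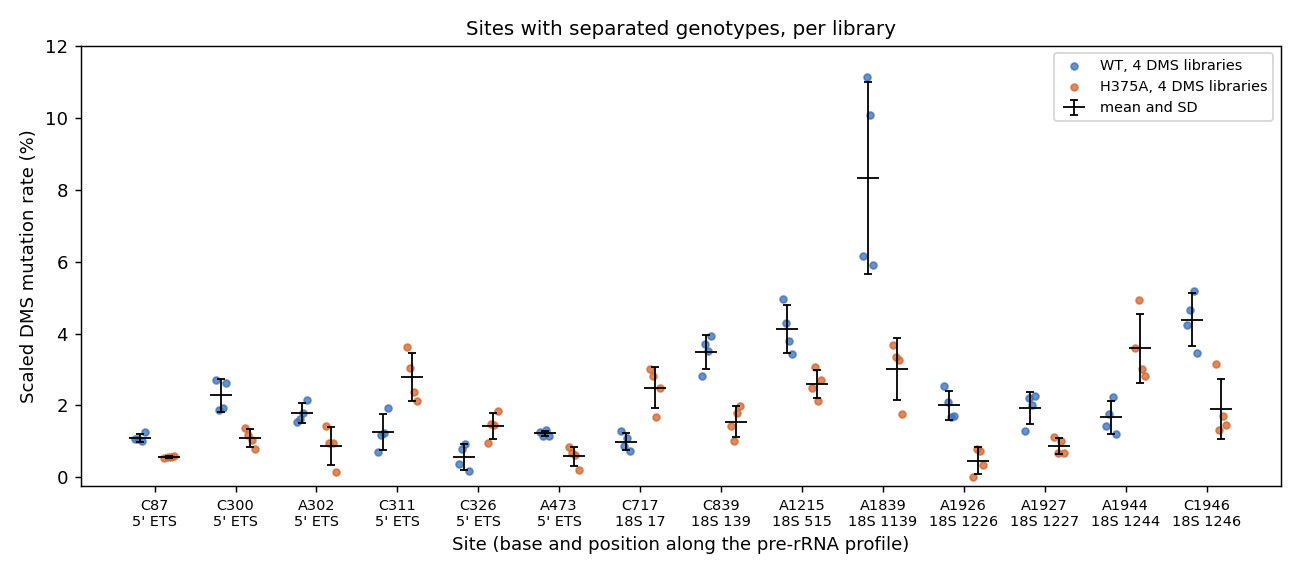
Scaled DMS mutation rate in percent at the 14 named sites, with a point for each of the 4 WT and 4 H375A DMS libraries and bars for the mean and SD. The libraries of the genotypes do not overlap at any of these sites, and A1839 shows the widest gap, 8.32% against 3.01% on average.

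Of the 26 called sites, 14 had no overlap between genotypes, and 12 overlapped. Over all 725 sites, 42 did not overlap, or 5.79% where chance gives 2.86%, and 87 had an unadjusted p under 0.05 where chance gives 36.25. The number of calls depended on the model. It was 9 with DESeq2, which gave no adjusted p at 281 of the 725 sites, and 10 with a quasi-binomial model per site. With limma on background-subtracted rates it was 1, and with the genotype by treatment interaction or with all libraries thinned to the shallowest 0. It also fell to 11 without H375A replicate 3, to 14 without WT replicate 2 or WT replicate 3 and to 16 without H375A replicate 2. All 26 sites kept their direction in each of these settings. The median ratio of their log2 change to that of the main fit was 0.961 with the interaction and 0.866 when thinned. It was 1.02 with DESeq2 and 1.01 with the quasi-binomial model. These fits use the same reads, so the ratios do not check the calls. Of the named sites, A1839, C1946, C311, C717 and C839 stayed called with any library left out.

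Averaged over regions, reactivity differed little. The 5' ETS had the lowest limma p of the 6 domains, with a mean scaled rate of 1.66% ± 0.04 in WT and 1.57% ± 0.02 in H375A (SD, n = 4; log2 change -0.086, SE 0.028, limma adjusted p = 0.075), which did not pass, although it did without WT replicate 4 (adjusted p = 0.026). Every H375A library was below every WT library there (exact permutation p = 0.0286, not adjusted). The domains of 18S changed by -0.034 to 0.030 on the log2 scale and ITS1 by 0.089 with an SE of 0.090. These values are relative to the median SSU site. With scaling from 25S sites, which shifts all sites by -0.13, the 5' (-0.096), central (-0.13) and 3' major (-0.11) domains and ITS1 (-0.038) turned negative, and no domain passed (limma adjusted p of 0.0972 to 0.747). The 5' ETS and the 3' minor domain, negative already, fell further by the same shift. No 100-nt window passed (lowest limma adjusted p = 0.244), while 2 did with scaling from 25S sites. Without adjustment, the exact permutation p was 0.0286 at positions 401 to 500, 501 to 600 and 2401 to 2500, lower in H375A. It was also 0.0286 at 1601 to 1700 and 2101 to 2200, higher in H375A. The U14 snoRNA guides early folding and a modification of 18S, and Has1 is known for its part in releasing it from pre-rRNA. At its pairing site, 18S nucleotides 83 to 95, 5 of 7 A and C sites were tested, none was called, and 0 were called when adjusted over the list alone. The mean scaled rate there was 1.06% ± 0.09 in WT and 1.24% ± 0.15 in H375A (log2 change 0.22, SE 0.11, exact permutation p = 0.114, n = 4). That the site did not pass depended on 1 library, H375A replicate 3. Without it the rise was larger, with a log2 change of 0.29 and an exact permutation p of 0.0286, the smallest that 4 libraries against 3 allow.

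Without DMS, none of 554 sites differed between genotypes by edgeR (lowest adjusted p = 0.997) and none by DESeq2; 8 had an unadjusted p under 0.05 where chance gives 27.7. With a term for replicates 1 and 4 against 2 and 3, a division seen in these libraries and added afterwards, 1 site was called. It was U1891, the modified base of helix 31 a mark of mature 18S, which was lower in H375A (log2 change -1.88, SE 0.39, edgeR adjusted p = 0.0221) and also had the lowest unadjusted p without the term (0.0029). A model chosen beforehand, with a term for each replicate number, called the same site. Only 10 of the 26 sites called with DMS had enough mutated reads to be in this test. In 25S, which is not a part of the SSU processome and served as a comparison stretch, 1 of 295 sites was called. A4476 fell from 15.6% ± 4.6 to 7.62% ± 1.20 (SD, n = 4; log2 change -1.05, SE 0.20, edgeR adjusted p = 3.98e-05), and 30 sites had an unadjusted p under 0.05 where chance gives 14.75. At the depth of 25S few changes could be recovered in simulated data, and with a depth minimum of 50 reads 10 sites were called; without WT replicate 1, WT replicate 2 or H375A replicate 2 there were 2.

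Coverage gave the depth of each part of the pre-rRNA, whether from the particles or from other rRNA in the purification. Mean depth of the 5' ETS up to the A0 site was 2.81 times that of 18S in WT and 2.14 times in H375A (log2 difference -0.39, exact permutation p = 0.143, n = 4). Depth of 25S was 0.428 of that of 18S in WT and 0.292 in H375A, a log2 difference of -0.55 with every H375A replicate below every WT replicate (exact permutation p = 0.0286, adjusted 0.2). For 5.8S the ratios were 0.445 and 0.320 (exact permutation p = 0.057, adjusted 0.2). ITS1 between the D and A2 sites had 0.382 and 0.474 of the 18S depth, and from A2 to B1 0.147 and 0.191 (exact permutation p = 0.314 and 0.171). From A0 to A1 the ratio was 1.15 in both genotypes, and for ITS2 it was 0.107 and 0.103. No region passed after adjustment over 7 regions, but the adjusted 0.2 of 25S is the smallest that a lone region can reach. Set against the WT replicate of the same number, H375A was lower in 4 of 4 cases for the 5' ETS up to A0, 5.8S and 25S and higher in 4 of 4 for D to A2 and A2 to B1, although an exact test of 4 pairs gives no p below 0.125.

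Modified bases that alter reverse transcription without DMS served as marks of mature rRNA in the untreated libraries. The m1acp3-pseudouridine of helix 31 (position 1891, 18S 1191), whose last modification step takes place on late cytoplasmic subunits, read 8.32% ± 4.54 in WT and 2.28% ± 1.81 in H375A (SD, n = 4, exact permutation p = 0.0857, adjusted 0.305). It was 1.73% in WT replicate 1 and 8.97% to 11.6% in the other WT replicates, against 0.256% to 4.17% in H375A, at depths of 229 to 4409 reads. Pooled over replicates, it was 10.1% (95% Wilson interval 8.96% to 11.3%) in WT and 3.67% (3.23% to 4.17%) in H375A, and it was lower in H375A at each of the 4 replicate numbers. As given above, it passed in the untreated site test once differences among replicates were in the model, so the 18S sites above were compared between libraries that differed in this mark under such models. The second m3U of 25S (position 6094) read 54.4% ± 2.8 in WT and 40.5% ± 2.3 in H375A with no overlap (exact permutation p = 0.0286, adjusted 0.229, the smallest that a lone mark can reach over 8 marks). The first m3U (position 5885) read 54.9% ± 2.8 and 39.8% ± 11.5 at depths of 18 to 451 reads (exact permutation p = 0.114). The m1A bases of 25S read 74.5% ± 4.2 and 76.2% ± 0.6 at position 3896 (exact permutation p = 0.486) and 57.1% ± 4.2 and 54.8% ± 6.5 at position 5393 (exact permutation p = 0.543). The dimethyl-adenosines and the acetylcytidine of helix 45 read between 0.308% and 0.868% on average in either genotype, near the rates of unmodified bases.

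**Figure D3:**
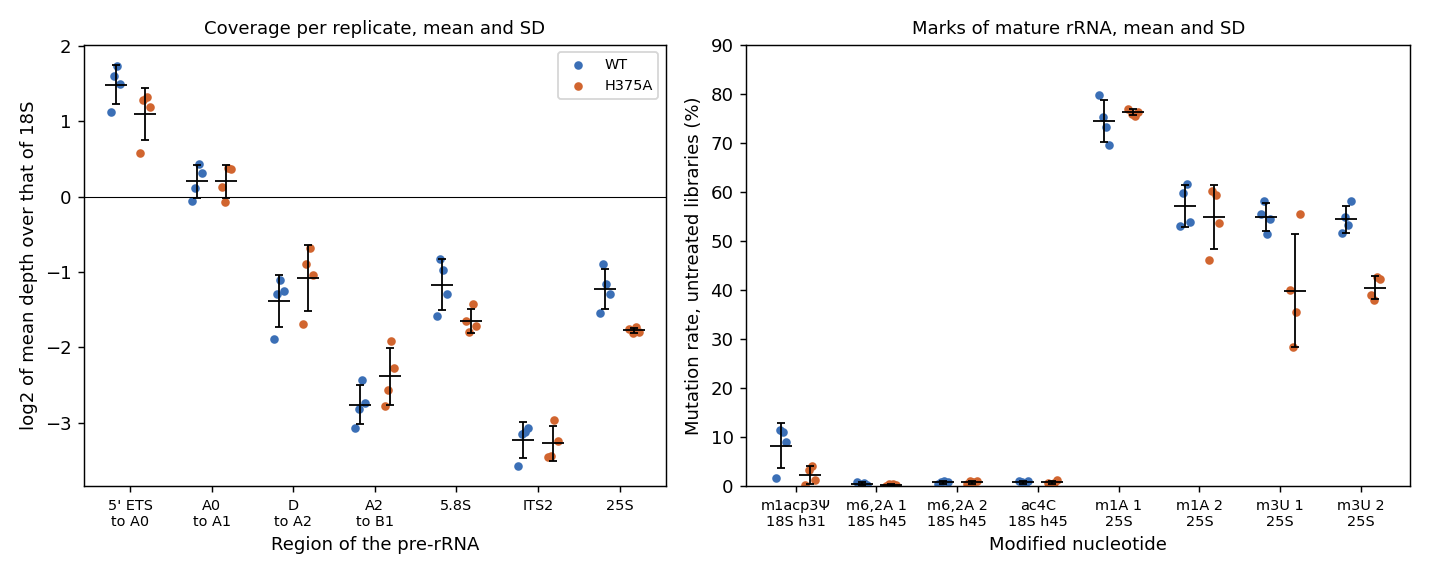
Left, log2 of mean effective depth of each pre-rRNA region over that of 18S, per replicate with the untreated and DMS library averaged; right, mutation rate in percent at modified bases in the untreated libraries; points are the 4 replicates of each genotype, bars the mean and SD. The 25S ratio and the second m3U of 25S separate the genotypes, 0.428 against 0.292 and 54.4% against 40.5%.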

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

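Among the tests below, the count of called 5' ETS sites against mature ribosomes and both tests of the m3U marks were chosen after their results had been seen. No library passed Dixon's test for an outlying value in any of 88 group values of base rates, coverage, marks, domains, the U14 site and named sites, where chance gives about 4.4. With 4 libraries the test asks for a gap of most of the group's range, and several values came near, among them replicate 1 for the DMS rate at A (gap over range 0.815 in WT and 0.766 in H375A), so replicate 1 can stand apart without passing. No difference between genotypes in the DMS effect by base was detected (exact permutation p of 0.343 to 0.8).

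The 26 sites called with DMS were set against all 35 splits of the 8 DMS libraries into 4 and 4. Only 1 split, the real one, gave as many calls, and the highest other split gave 8. This argues against chance but cannot exclude it, since no result over 35 splits can be rarer than 1 of 35. The other splits also mix the genotypes, so they are not free of a difference between them. For 25S, 3 of 35 splits gave 1 call or more, and the highest other gave 1, so chance is not excluded. The untreated comparison, the domains and the windows had 0 calls, which 35 of 35 splits must match, so their splits say nothing about chance; the highest other splits gave 23 sites, 1 domain and 1 window. The split with 23 untreated calls parted replicates 1 and 4 from replicates 2 and 3 of both genotypes, which points to a structure of the samples that the labels do not name. The division coincides with sequencing depth, since replicates 1 and 4 had untreated median depths over 18S of 314 to 613 reads and replicates 2 and 3 of 1151.5 to 4933, and whether it comes from depth or from a shared origin was not tested. With a term for this division, added after it was seen, 33 SSU sites were called with DMS, including all 26.

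The called sites could come from a few libraries or from more mature ribosomes in the WT purifications. Without the far deeper H375A replicate 3, the median signed log2 change of the 26 sites was 1.11 times that with it (1.06 against 0.96), although calls fell to 11, of which 10 were shared; without replicate 1 of both genotypes it was 1.00 times (1.0015), with 35 calls. Leaving out these libraries thus did not shrink the changes. The 26 sites had been chosen with the remaining reads as well, so neither ratio can exclude these libraries as the cause of the calls. The DMS libraries of replicate 1 held 12708 (WT) and 9652 (H375A) mutated reads, against 166512 in H375A replicate 3, so the ratio without them could hardly move. Mature ribosomes lack the 5' ETS, and 17 called sites lay there, which argues against them for that part. For the 9 called sites of 18S, the helix 31 mark as a covariate left 0.788 of the median change (0.737 to 0.843 with a library left out) and an unadjusted edgeR p under 0.05 at 7. The bound of 0.75 had been set before the ratio was seen. The demand that it also hold with each library left out was added afterwards, and without it the label would have been against mature 18S. Neither rule could exclude mature 18S. The covariate, with untreated and DMS reads pooled, ran from 2.82% to 13.3% in WT and from 0.686% to 4.45% in H375A. It thus followed the genotype in part and carried counting error. The mark itself was lower in H375A in the untreated libraries once differences among replicates were modelled (edgeR adjusted p = 0.0221 with the division added afterwards, and past the threshold with the planned term for replicate numbers), as more mature 18S in WT would make it. The pooled intervals of the helix 45 marks overlapped, but these marks read under 1% (0.474% to 0.913%), too near the background to inform on mature 18S. Coverage, where no region passed and a lone one could not, went both ways. The 5' ETS over 18S was higher in WT (2.81 against 2.14), against more mature 18S in WT. Other regions went with it, but all ratios share the depth of 18S, so they are not independent, and 25S and 5.8S do not measure mature 18S. In WT, 25S (0.428 against 0.292, exact permutation p = 0.0286, adjusted 0.2) and 5.8S (0.445 against 0.320) were higher. ITS1 was lower in WT from D to A2 (0.382 against 0.474) and from A2 to B1 (0.147 against 0.191). A0 to A1 and ITS2 hardly differed. With the range on both sides of the bound, mature 18S and the genotype cannot be told apart at these sites. The genotype remains open for all 26.

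The larger share of called sites in the 5' ETS could come from its depth. When the 5' ETS was thinned in each library by the ratio of its median depth to that of 18S, in 20 draws, called sites there fell from 17 to a median of 5.5 of 161, against 9 of 538 in 18S, and the median odds ratio fell from 6.91 to 1.99. The median Fisher's exact p rose from 3.08e-06 to 0.256, so with median depths matched the larger share no longer passed by the median p. By the median odds ratio it stayed somewhat larger, but the draws ran from 2 to 9 called sites of the 5' ETS. Depth can account for much of the concentration. A greater effect of the genotype on the 5' ETS than on 18S is not shown, and stays open.

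The m3U marks of 25S averaged lower in H375A, but neither passed (exact permutation, adjusted p 0.305 and 0.229), and the genotypes overlapped at the first. Counting noise is argued against, as the whole of it, since the pooled 95% Wilson intervals did not overlap at 2 of the 2 marks (51.7% to 56.8% in WT and 39.3% to 43.7% in H375A at the second), though these intervals leave out the spread between replicates. A larger share of unmodified 25S in H375A would lower m1A marks alike, but the log2 ratio of H375A to WT was -0.014 for m1A and -0.47 for m3U, a difference of 0.452 with an SE of 0.145, which argues against it. Particles that carry m1A but not yet m3U, less m3U in mature 25S, and chance among 8 marks stay open.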

How the results depend on the processing

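Alternatives chosen after seeing the data were depth minima of 50 and 200 reads, the robust dispersion, thinning, the whole profile, leaving out replicate 1 of both genotypes, the term for replicates 1 and 4 against 2 and 3, pairs of DMS and untreated libraries, and marks from untreated and DMS reads pooled. Unless stated, the cause of a change was not tested. The 26 SSU calls (8 rose, 18 fell) became 0 with the interaction, 1 with limma on background-subtracted rates and 10 with the quasi-binomial model. With DESeq2 they became 9, but 281 of 725 sites had no adjusted p there. When thinned to the shallowest library, which removes most reads, 0 sites were called. Without each replicate the calls ran from 11 to 30. Other settings gave 21 to 35. Scaling from 25S sites, which shifts all sites by -0.13 (log2), gave 6 that rose and 23 that fell. No named site changed sign; their calls were kept in 96 and lost in 24 fits without a replicate, and kept in 175 and lost in 60 other fits, A4476 of 25S included. A depth minimum of 5000 left no site. The untreated test called 1 site, U1891 of helix 31, with the replicate block (log2 change -1.72, edgeR adjusted p = 5.24e-07) and the same 1 with the term for replicates 1 and 4 (adjusted p = 0.0221), against 0.997 without either. In 25S, 10 sites were called with a depth minimum of 50, and 1 to 2 without each replicate.

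With the median rate, DMS minus untreated was 0.609 (WT) and 0.624 (H375A) percentage points at A, 0.206 and 0.213 at C, 0.0467 and 0.0591 at G and 0.0365 at U in WT, none passing (adjusted p 0.069 to 0.086). H375A minus WT turned to 0.0080 at A and 0.0097 at G, and without each replicate ran from -0.120 to 0.0368 at A and from -0.0161 to 0.0221 at C. Without a replicate, DMS against untreated is 3 libraries against 3, which cannot pass.

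Domain changes near 0 turned sign (log2): without scaling, 3' major -0.0089 and central -0.026; with 25S scaling, 3' major -0.11, 5' -0.096, central -0.13 and ITS1 -0.038, with 2 windows called; with background-subtracted rates, 3' minor 0.013 and central -0.013; with the mean of log2 rates, 3' minor 0.021. Without each replicate the central domain ran from -0.028 to 0.028 and the 5' ETS from -0.099 (without WT replicate 4, adjusted p = 0.026) to -0.071; over its other alternatives adjusted p was 0.097 to 0.98. Coverage from A0 to A1 turned to 0.0057 (untreated only) and 0.0066 (median depth), and ITS2 to 0.039 (DMS only); without each replicate they ran from -0.086 to 0.092 and from -0.16 to 0.013. The second dimethyl-adenosine turned to -0.261 points in DMS libraries and -0.110 with the untreated and DMS reads of each replicate pooled. Without each replicate it ran from -0.0792 to 0.188 points, the acetylcytidine from -0.25 to 0.0300 and the second m1A from -4.02 to 0.636. The U14 site ran from 0.16 to 0.29 (log2), passing only without H375A replicate 3 (exact permutation p = 0.0286, otherwise 0.0857 to 0.486).

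The DMS profiles did not show that replicate numbers pair the genotypes: correlations of same-numbered libraries were 0.16, 0.069, 0.17 and 0.0039, not all above 0.1, and of the WT libraries only replicates 1 and 3 correlated best with their own number. The features that replicate 1 of both genotypes shared, and the division of the untreated libraries, leave a shared origin of some numbers open. With the replicate block 26 SSU sites were called (10 rose, 16 fell), 24 of them shared. Depth limits what can be found. In simulated data 65% of 2-fold changes were recovered in the SSU part, with 200 of 725 sites changed. In 25S, with 60 of 295 sites changed, 3.33% were. A smaller share of changed sites, as among the calls, was not simulated.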

Other observations

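The test of U3 segments below was chosen after the called sites had been seen. U3 pairs through its hinges with the 5' ETS at positions 281 to 291 and 470 to 479, and through box A with the 5' end of 18S at positions 709 to 716. These segments were entered from general knowledge of U3. They held 7 tested sites, and 3 of them fell in H375A: A283 from 4.59% ± 1.44 to 2.35% ± 1.01, A473 from 1.22% ± 0.08 to 0.581% ± 0.268, and A474 from 1.52% ± 0.60 to 0.830% ± 0.347 (SD, n = 4). Outside them 15 of 718 sites fell (Fisher's exact test, two-sided, p = 0.000424), and within the 5' ETS alone it was 3 of 6 against 8 of 155 (Fisher's exact test, p = 0.0043). All 7 sites had a log2 change below 0, with a median of -0.71, against 47.5% of the sites outside. Just outside the first segment, A280 rose from 1.36% ± 0.65 to 2.49% ± 0.64 and A295 from 2.05% ± 0.28 to 3.46% ± 1.20. C717, the base next to the end of the box A segment, rose from 0.991% ± 0.243 to 2.50% ± 0.58. The shared direction inside the segments thus depends on where their ends were set. Because the segments were entered after the calls had been seen, these p-values only describe the pattern, and whether U3 pairing differs between the genotypes was not tested. A473 and A474 are neighbours, and groups overlapped at A283 and A474.

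Replicate 1 of both genotypes shared several features. The mean DMS rate at A was 0.991% in WT and 0.961% in H375A, against 1.22% to 1.34% in the other libraries. The effective depth was 91.7% and 91.6% of the read depth in these DMS libraries, against 88.3% to 88.8% in the rest. The helix 31 mark in the untreated libraries was 1.73% and 0.256%, the lowest of each genotype.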
